A study of Mus musculus with 25 samples.

How the data were processed

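RNA from whole liver of mice with a hepatocyte-specific deletion of Mcl-1, of hemizygous and wild-type mice and from the tumors of the deleted mice was measured on 25 single-colour arrays with Cy3 label. The labels give genotype, age, tissue and an animal number, and samples were grouped by these alone into 8 groups. At 2 months there were 2 wild-type, 3 hemizygous and 3 knockout mice. At 12 months there were 3 wild-type mice and 4 knockout mice, and 3 more knockout mice were 8 months old. Each of these 7 older knockout mice gave a tumor and a non-tumor sample, paired by the animal number. The labels give neither the sex of the mice nor the part of the gene that was deleted.

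The deposited array files hold intensity values written by Agilent Feature Extraction, one value per spot, per the file headers. Their processed signal is background-subtracted and detrended within the array and not normalised between arrays. The authors also deposited a series matrix of log2 values. The matrix was checked against the array files: on every array its values ranked as the log2 of the uncorrected median signal did (lowest Spearman correlation 0.99999), and its medians lay between 6.57 and 6.58, so the matrix values follow the signal without background subtraction. How they were normalised between arrays was not tested. The submitters' processing notes name limma without saying what it was used for.

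Each array held 43379 non-control spots for 41174 probes, and the mean of log2 processed signal was taken over the spots of a repeated probe that carried no outlier mark. Probes were named by matching the accession printed with each probe to the RefSeq table of assembly GRCm38.p6, which named 24375 probes (59.2%) and 17016 symbols. The other 16799 probes carry transcripts without a symbol and stayed in the tests. Each gene was represented by its probe with the highest mean signal. A gene was kept when its probe was well above background on at least as many arrays of the fit as the smallest group holds, which is 2 of 18 or 3 of 14. Log2 processed signal minus the array's 75th percentile is called the level below.

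Differences were tested with limma 3.58.1 (empirical Bayes moderated, two-sided) in R 4.3.3. The first model took the 18 arrays without tumor tissue as 6 groups, with 12 residual degrees of freedom, and served 7 comparisons. The second took the 14 arrays of the 7 animals with tumors, with the animal as a fixed block and 6 residual degrees of freedom, and served 2 comparisons. P values were adjusted by Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05. Changes are on the log2 scale with the standard error (SE) of the model.

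Gene lists, 31 in number, were written before the data were examined, as were the models, the tests, most of the alternative settings and the rule for naming genes. Each list with at least 5 measured genes was tested with camera of limma at a preset correlation of 0.01, and again with a correlation estimated from the data, adjusted over the lists of a comparison. Counts of single list members are given over all genes and adjusted over the list alone. List means per array or per animal were compared by exact permutation, two-sided. The smallest p this allows is 0.1 for 3 against 2 or 3 against 3 arrays, 0.0286 for 4 against 3 and 0.0156 for 7 pairs.

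The rule for naming genes puts Mcl1 first. It adds up to 8 genes each way in 3 main comparisons and up to 4 each way in the others, from those past the threshold whose groups do not overlap (for pairs, with the same sign in all 7 animals), well above background on every array of the higher group and with a symbol. It further adds up to 4 members with the smallest p from each list described, and a panel of 16 genes fixed in advance. H19, Mki67 and Ccnd1 of that panel were not tested under a symbol. Where no array of a group was well above background, the change is given as a bound. Top2a, Cx3cr1 and Cd8a were well above background on part of the wild-type arrays only, so the sizes of their changes are uncertain.

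The pairing was checked on levels centred within age and tissue: the tumor correlated most with the non-tumor sample of its own animal in 5 of 7 animals (r = 0.23 to 0.61), and in animals 1347 and 793 (r = 0.14 and 0.27) another sample correlated more. The model was tested on simulated data with known changes added. It recovered 38.7% of genes changed by 2 log2 units and 64.0% of those changed by 4 in knockout against wild-type at 2 months, 52.7% and 83.3% at 12 months, and 77.3% and 99.3% in tumor against non-tumor. Overlaps between comparisons that share arrays were set against simulations without any effect.

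Alternatives were normexp background correction (offset 50) with quantile normalisation, quantile normalisation of the processed signal, the series matrix values, no filter, a filter on every array, the mean of all probes, trend and robust options, slide or scan day as a block, all arrays in 1 model, only the groups compared, no animal block, the Xist level as a covariate, and leaving out each animal. The normexp alternative used the median signal of the spot, because the files hold no mean signal. Chosen after the data were seen were a model without the 3 arrays of the second scan day and the slide block and Xist covariate in the list tests.

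The share of probes well above background was 60.3% to 84.9% per array (median 66.0%), the signal was 2.65 to 5.55 times the local background, and no array held a saturated spot. The number of arrays limits the precision. No array was left out. A few genes that the rule names are not reported here.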

Results

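Transcript levels in whole liver were measured on 25 arrays to ask how the liver changes when hepatocytes lack Mcl-1, a BCL-2 family protein that protects cells from apoptosis, and how the tumors of these mice differ from the liver around them. Wild-type (n = 2), hemizygous (n = 3) and knockout (n = 3) mice were 2 months old. Wild-type (n = 3) and knockout (n = 4) mice were 12 months old, and 3 further knockout mice were 8 months old. Tumor and non-tumor tissue came from each of the 7 older knockout mice. Per array, 60.3% to 84.9% of probes were well above background, with wild-type animal 641 at 84.9% and the next array at 76.3%. Arrays lay on 8 slides scanned on 2 days. Xist, the transcript of the inactive X chromosome, was well above background at 2 months on 1 of 2 wild-type, 3 of 3 hemizygous and 1 of 3 knockout arrays, so sex was not balanced between groups.

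Mcl1 itself (probe A_51_P238786, GRCm38.p6 chromosome 3, 95656944 to 95663179) fell by 2.46 on the log2 scale (SE 0.37, adjusted p = 0.038) in knockout against wild-type liver at 2 months. Its level was 1.75 (SD 0.29, n = 3) in knockout and 4.21 (SD 0.34, n = 2) in wild-type mice, a 5.49-fold difference, and a second probe differed by -3.20. Hemizygous mice lay between, with 3.29 (SD 0.21, n = 3). At 12 months the level was 2.53 (SD 0.17, n = 4) in non-tumor knockout liver and 4.22 (SD 0.34, n = 3) in wild-type liver. Tumors held 2.27 (SD 0.56, n = 7) and non-tumor tissue of the same animals 2.49 (SD 0.44, n = 7). No array of a knockout mouse reached the level of any wild-type or hemizygous array.

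**Figure D1:**
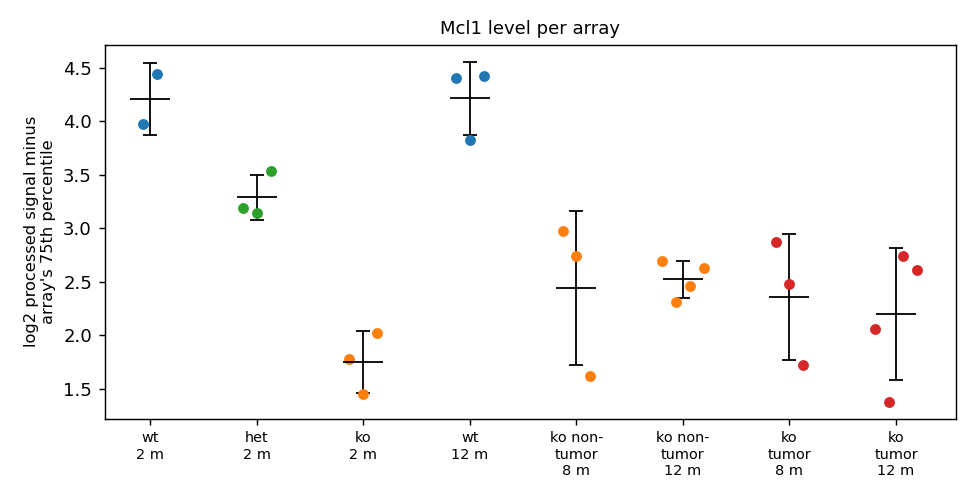
Mcl1 level per array (log2 processed signal minus the array's 75th percentile, vertical axis) in each of the 8 groups (horizontal axis), with points for arrays and bars for the mean ± SD. Knockout liver at 2 months had a mean of 1.75 against 4.21 in wild-type liver.

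Knockout against wild-type liver at 2 months asks what loss of Mcl-1 does in young animals. Transcripts of cell division were higher in knockout liver: all 27 measured mitosis genes had positive changes, with a median of 2.40 (adjusted p = 4.2e-17, and adjusted p = 0.26 with an estimated correlation). Among them Cdc20 differed by 3.48 (SE 0.99), the spindle factor Tpx2 by 2.94 (SE 0.95) and the kinase Aurka by 2.36 (SE 0.67). Macrophage markers were also higher, 22 of 22 with a median of 1.38 (adjusted p = 2.5e-13, and adjusted p = 0.25 with an estimated correlation), including Trem2 by 3.63 (SE 0.95) and the chemokine receptor Cx3cr1 by 2.39 (SE 0.78). Genes of stellate cells and matrix had a median of 1.23 with 21 of 23 above 0 (adjusted p = 8.3e-12, and adjusted p = 0.25 with an estimated correlation), among them Loxl2 at 1.73 (SE 0.40) and the muscle actin Acta2 at 1.23 (SE 0.41). Neutrophil markers had a median of 2.15 with 10 of 11 above 0 (adjusted p = 1.7e-06, and adjusted p = 0.26 with an estimated correlation), among them S100a9 at 3.92 (SE 0.67, adjusted p = 0.056).

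Of single genes, 6 of 26447 passed the threshold in knockout against wild-type liver at 2 months, 2 higher and 4 lower. Tubb2a, a beta-tubulin on chromosome 13, rose by 3.59 (SE 0.51, adjusted p = 0.031). Besides Mcl1, the translation repressor Eif4ebp3 fell by 2.98 (SE 0.39), Gpcpd1 by 2.94 (SE 0.40) and Bnip3, a BCL-2 relative of mitochondria, by 1.86 (SE 0.26), each with adjusted p = 0.029. The sixth, a transcript without a symbol (probe A_51_P361620, chosen after its values were seen), was at least 36.6-fold higher. Over all genes none of the 27 mitosis genes and none of the 22 macrophage markers passed limma's test, and adjusted over the list alone 18 mitosis genes, 2 macrophage markers, 3 stellate and matrix genes and 3 neutrophil markers did. From the fixed panel, the stress hormone Gdf15 differed by 2.69 (SE 0.81, adjusted p = 0.34), the cell cycle inhibitor Cdkn1a by 1.74 (SE 0.72, adjusted p = 0.50), Top2a by 2.51 (SE 1.04, adjusted p = 0.51), and the fetal protein Afp by 1.15 (SE 0.76, adjusted p = 0.71).

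Further lists passed camera's test at 2 months with smaller shifts. Higher were chemokines and cytokines (median 0.92; Il1b 2.52, Ccl2 2.96), fetal and HCC-associated genes (1.22; Ly6d 4.54, Tff3 3.68), NRF2 targets (0.85; Hmox1 1.65, Gclc 1.13), immediate early genes (0.83), acute phase proteins (0.34; Saa2 3.20, Saa1 2.91), cholangiocyte and progenitor markers (0.82), S phase genes (0.47), T and NK cell markers (0.36), DNA damage response genes (0.21) and p53 targets (0.16). Lower were fatty acid oxidation and PPAR-alpha targets (-0.69), bile acid synthesis and transport (-0.47), hepatocyte identity and secreted proteins (-0.30) and clock genes (-1.10). Within the oxidation list Cpt1a, the entry enzyme of mitochondrial oxidation, differed by -1.46 (SE 0.36) and Angptl4 by -3.13 (SE 0.81), while Pdk4 went the other way at 3.11 (SE 0.83). Among clock genes Arntl differed by 4.30 (SE 0.93) and Per1 by -2.57 (SE 0.79), opposite arms of the daily cycle. These 14 lists had adjusted p = 3.0e-07 to 0.045 (adjusted p = 0.12 to 0.57 with an estimated correlation).

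The other 13 lists did not pass at 2 months. They were the BCL-2 family (median 0.01), death receptor and NF-kB genes (-0.04), unfolded protein and amino acid stress (0.45), interferon response (0.16), beta-catenin and pericentral genes (-0.12), periportal genes (-0.12), cholesterol synthesis (-0.16), lipogenesis (-0.36), male-biased (-0.14) and female-biased (-1.32) liver genes, and markers of B and plasma cells (0.69), endothelial cells (0.16) and erythroid cells (-0.60). For death receptor and periportal genes the median was negative and the mean (0.17 and 0.05) and the test's direction positive.

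The count of changed genes at 2 months rested on every array compared: it was 2 without wild-type 31 or 34, 0 without knockout 137, 64 or 69, and 24 without non-tumor animal 934 of the shared model. With the slide as a block 40 genes passed, 0 of them among the 6, Mcl1 differed by -2.07, and the medians were 1.303 for mitosis genes (adjusted p = 0.030), 1.15 for macrophage markers (0.021), 0.75 for stellate and matrix genes (0.10) and 0.64 for fetal and HCC-associated genes (0.72). Over the alternatives, the slide block included, Tubb2a differed by 3.26 to 3.92, Eif4ebp3 by -3.51 to -2.67, Gpcpd1 by -3.23 to -2.64 and Bnip3 by -1.99 to -1.34. No slide held wild-type and knockout mice of 2 months, and on the slide with 1 knockout and 2 hemizygous arrays the knockout array differed by 1.65 in the mean of mitosis genes, 1.27 in that of macrophage markers and -1.39 in Mcl1. Sex differed on that slide too: Xist was well above background on both hemizygous arrays and not on the knockout array, and the means of male-biased and female-biased genes differed by 3.79 and -4.80. Of the smaller calls, 9 ended when a single array was left out: the highest adjusted p without wild-type 34 was 0.13 for T and NK cell markers, 0.12 for clock genes, 0.14 for bile acid genes, 0.15 for hepatocyte genes and 0.055 for cholangiocyte markers, without wild-type 31 it was 0.11 for p53 targets, and without knockout 64 it was 0.86 for S phase, 0.51 for DNA damage and 0.11 for acute phase genes.

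**Figure D2:**
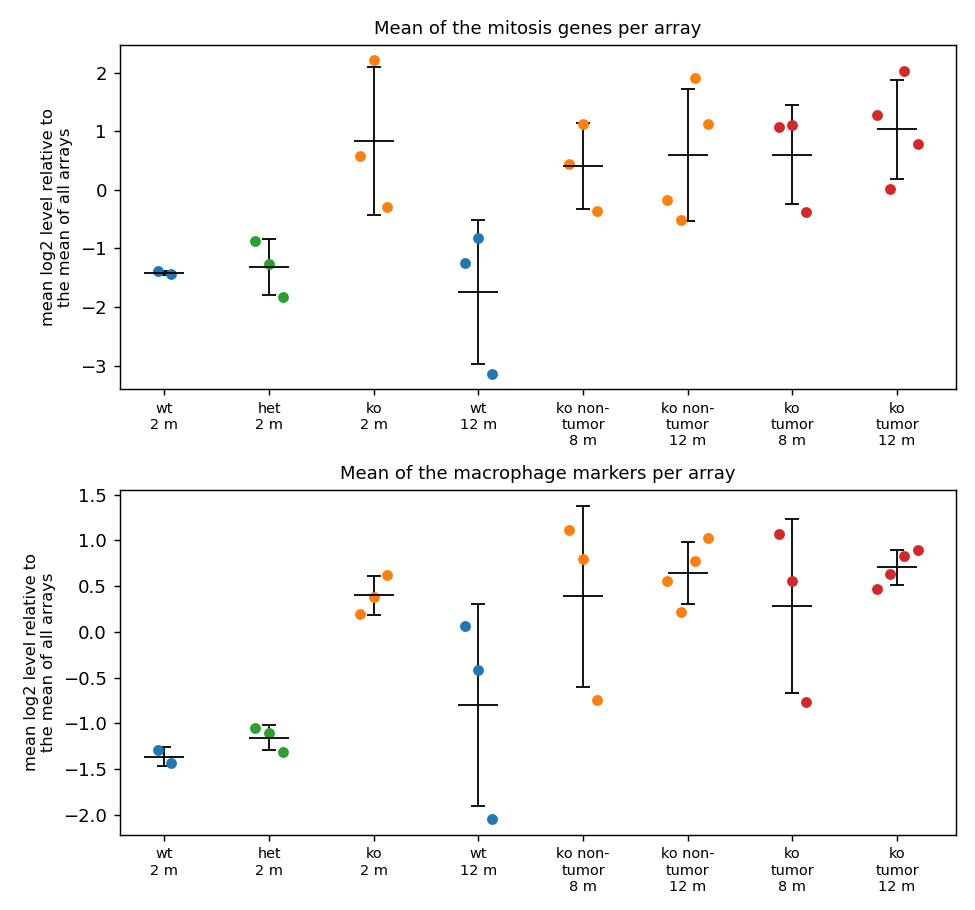
Mean level per array of the mitosis genes and of the macrophage markers (log2, centred per gene, vertical axes) in each group (horizontal axis), with points for arrays and bars for the mean ± SD. At 12 months the mitosis means of the 4 non-tumor knockout arrays lay between -0.51 and 1.91 and those of the 3 wild-type arrays between -3.14 and -0.82.

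Knockout against hemizygous liver at 2 months compares loss of both Mcl1 alleles with loss of 1. The neutrophil calprotectin genes rose, S100a9 by 4.202 (SE 0.60, adjusted p = 0.027) and S100a8 at least 15.8-fold, though with normexp and quantile normalisation S100a8 differed by 1.11 (adjusted p = 0.12) and in the series matrix by 2.25. Tubb2a rose by 3.31 (SE 0.46) and the growth-restraining imprinted gene Phlda2 by 3.37 (SE 0.48), both with adjusted p = 0.027, though with normexp and quantile normalisation Phlda2 differed by 1.53 (adjusted p = 0.052). The glucocorticoid target Fkbp5 fell by 3.21 (SE 0.52, adjusted p = 0.044), the kinase Map2k6 by 2.35 (SE 0.31, adjusted p = 0.027), Gpcpd1 by 2.32 (SE 0.36) and Eif4ebp3 by 2.22 (SE 0.35). Mitosis genes were higher in 27 of 27 (median 2.36, adjusted p = 6.0e-18, and adjusted p = 0.26 with an estimated correlation), and so were 22 of 22 macrophage markers (median 0.92, adjusted p = 8.6e-11, and adjusted p = 0.26 with an estimated correlation).

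In all, 14 of 26450 genes passed in knockout against hemizygous liver, 9 higher and 5 lower, and Mcl1 differed by -1.54 (SE 0.33, adjusted p = 0.13; second probe -2.30). Adjusted over the list alone, 16 mitosis genes, 6 macrophage markers and 3 neutrophil markers passed, against 0, 0 and 2 over all genes. Lower lists included cholesterol synthesis (median -0.54, 18 of 19 below 0, adjusted p = 1.75e-05, and adjusted p = 0.36 with an estimated correlation) and clock genes (-1.19, adjusted p = 0.0043), with 8 clock genes lower and 2 higher adjusted over the list alone (adjusted p = 0.092 for the clock list with an estimated correlation). Fatty acid oxidation (median -0.40), lipogenesis (-0.53), bile acid (-0.42), female-biased (-3.14) and endothelial genes (-0.32) were lower as well. Their adjusted p in camera was 6.2e-05 to 0.032 (0.26 to 0.55 with an estimated correlation). Knockout and wild-type liver had differed in 4 of these 14 genes, Tubb2a, Bnip3, Eif4ebp3 and Gpcpd1, in the same direction. Simulations of the shared knockout arrays without any effect gave 0.05 such genes. The adjustment lets few genes pass where nothing changes, so that value does not measure what the shared arrays add. Across genes the 2 sets of changes had r = 0.75, against 0.45 in those simulations. The count was 0 without hemizygous 27, 28 or 30 or knockout 64, 5 without knockout 69, 7 without non-tumor 1347 or 1287 and 28 without non-tumor 934. With the slide as a block 41 genes passed, 0 of them among the 14, and the medians were 1.73 for mitosis genes and 1.02 for macrophage markers (adjusted p = 4.35e-06 and 1.24e-04). Over the alternatives, the slide block included, Tubb2a differed by 2.99 to 3.51, Gpcpd1 by -2.46 to -2.19, Eif4ebp3 by -2.51 to -1.97 and S100a9 by 2.96 to 4.56. Within the slide that held 1 knockout and 2 hemizygous arrays, where sex differed as well, S100a9 differed by 3.49, Tubb2a by 3.16 and Gpcpd1 by -2.24. Wild-type liver of 12 months had levels near those of knockout liver of 2 months in Fkbp5 (-0.55 against -0.63) and Map2k6 (-0.46 against -0.73). S100a9 had 0.50 against 1.20 and S100a8 -3.32 against -2.01, while Phlda2 had -4.21 against -0.72. Such levels of Fkbp5, Map2k6 and S100a9 thus also occurred without loss of Mcl-1. Whether age or the time of collection accounts for them was not tested.

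Hemizygous against wild-type liver at 2 months asks what loss of 1 allele does. Mcl1 differed by -0.92 (SE 0.37, adjusted p = 1.0). Cholesterol synthesis genes were higher in 19 of 19 (median 0.57, adjusted p = 5.5e-08), and endothelial markers in 16 of 16 (median 0.39, adjusted p = 2.1e-06). Stellate and matrix genes had a median of 0.43 (adjusted p = 2.6e-05), female-biased liver genes 1.91 and male-biased ones -1.37 (adjusted p = 4.3e-04 and 2.0e-04). Cholangiocyte and progenitor markers (median 0.27), macrophage markers (0.14) and lipogenesis genes (0.17) passed camera's test as higher too (adjusted p = 0.0073, 0.039 and 0.046). Each of these calls was lost with an estimated correlation (adjusted p = 0.78 to 0.88 with an estimated correlation). No gene passed limma's test, and 320 of 26446 had an unadjusted p under 0.05. With the Xist level as a covariate the medians of female-biased and male-biased genes became -0.04 and -0.56 (adjusted p = 0.38 and 0.11), and without wild-type 34 their adjusted p was 0.89 and 0.65. With the slide as a block 18 genes passed and the medians were 0.12 for cholesterol synthesis and 0.29 for endothelial markers (adjusted p = 0.94 and 0.89), and on the slide with 1 hemizygous and 2 wild-type arrays their means differed by 0.15 and 0.20.

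Non-tumor knockout against wild-type liver at 12 months asks what long-term loss of Mcl-1 does outside the tumors. Mitosis genes were higher in 27 of 27, with a median of 2.47 (adjusted p = 1.9e-17, and adjusted p = 0.18 with an estimated correlation), among them Prc1 at 3.10 (SE 0.82) and Cenpa at 2.03 (SE 0.49). Macrophage markers were higher in 22 of 22, with a median of 1.42 (adjusted p = 1.4e-10, and adjusted p = 0.18 with an estimated correlation), including the Kupffer cell gene Marco at 2.07 (SE 0.72) and Adgre1 at 1.91 (SE 0.61). Markers of T and NK cells had a median of 1.39 with 16 of 18 above 0 (adjusted p = 1.5e-05, and adjusted p = 0.26 with an estimated correlation), among them the co-receptor Cd8a at 2.69 (SE 0.61) and Gzmb at 2.13 (SE 0.60). Their means per array overlapped, with -1.50 to 0.62 in wild-type and 0.29 to 1.43 in knockout liver. Scan day limits every list of this comparison, since some wild-type arrays and no knockout array of it were scanned on the second day. Interferon response genes had a median of 0.82 with 17 of 19 above 0 (adjusted p = 2.2e-07, and adjusted p = 0.18 with an estimated correlation), with Ifi44 at 2.38 (SE 0.47) and Ifit1 at 1.60 (SE 0.41).

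Fetal and HCC-associated genes had a median of 2.42 at 12 months with 14 of 16 above 0 (adjusted p = 3.95e-06), and S phase genes one of 0.75 (adjusted p = 1.3e-05). Tff3 differed by 6.09 (SE 1.42) and Golm1 by 2.58 (SE 0.73). Afp had a level of 1.19 (SD 1.40, n = 4) in knockout and -2.30 (SD 0.94, n = 3) in wild-type liver, a change of 3.50 (SE 0.64, adjusted p = 0.089). Fatty acid oxidation and PPAR-alpha targets were lower in 22 of 23 (median -0.72, adjusted p = 1.95e-06), with Ppara itself at -1.46 (SE 0.44) and Hadha at -1.06 (SE 0.23). Bile acid genes had a median of -0.41 (adjusted p = 0.012), including the uptake carrier Slc10a1 at -2.06 (SE 0.39) and Cyp8b1 at -3.95 (SE 0.92). These 4 calls were lost with an estimated correlation as well (adjusted p = 0.18 to 0.38 with an estimated correlation), and without wild-type 552 the adjusted p of bile acid genes was 0.21.

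Single genes past the threshold at 12 months numbered 5 of 26455. B3galnt1, a glycosyltransferase gene, rose by 3.68 (SE 0.47, and by 2.15 with normexp and quantile normalisation) and the lipid phosphatase Lpin2 fell by 2.70 (SE 0.36), both with adjusted p = 0.021, and Dmrta1 was at least 6.41-fold lower (adjusted p = 0.0033), though by 0.77 on the log2 scale with normexp and quantile normalisation and by 1.88 in the series matrix. Of the 2 without a symbol, chosen after their values were seen, probe A_51_P361620 rose by 5.46 (SE 0.80), a size that is uncertain because it was well above background on 1 of the 3 wild-type arrays, and probe A_52_P487040 fell by 1.26 (SE 0.18), each with adjusted p = 0.037. Mcl1 differed by -1.69 (SE 0.31, adjusted p = 0.089). Adjusted over the list alone, 22 mitosis genes, 11 macrophage markers, 6 T and NK cell markers, 8 fetal and HCC-associated genes and 9 interferon genes passed as higher, and 6 oxidation genes, 4 bile acid genes and 1 interferon gene as lower, where none of these passed over all genes. In exact permutation of list means, macrophage markers, interferon response genes, p53 targets, immediate early genes and cholesterol synthesis reached the smallest possible p of 0.0286 (adjusted p = 0.16). In the same exact permutation mitosis, fetal and fatty acid oxidation genes had p = 0.057, S phase and bile acid genes p = 0.11 and T and NK cell markers p = 0.14.

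The count at 12 months depended on single animals: without non-tumor animal 638 it was 2729 (1121 higher, 1608 lower), without wild-type 552, 641 or 1110 it was 51, 26 or 41, without non-tumor 1109, 702 or 793 it was 1, and without 8-month non-tumor animal 934 it was 33. No slide held both groups, 2 of the 3 wild-type arrays were scanned on the second day, and with the scan day in the model, where wild-type 641 alone carries the comparison, 3431 genes passed, 3365 of them lower.

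Wild-type mice of 12 and 2 months were compared for differences with age, though no slide held both ages and 2 of the 3 older arrays were scanned on the second day. Tubb2a rose by 3.65 (SE 0.51), the NK receptor ligand gene Raet1e by 4.36 (SE 0.60, and 2.89 with normexp and quantile normalisation) and Lrfn3 by 2.40 (SE 0.37), and Dmrta1 was at least 5.30-fold higher (log2 0.78 with normexp and quantile normalisation, 1.73 in the series matrix). Gpcpd1 fell by 3.20 (SE 0.40) and Eif4ebp3 by 2.86 (SE 0.39). Gdf15 differed by 3.07 (SE 0.81, adjusted p = 0.20), and Mcl1 by 0.01 (SE 0.37; second probe -0.47). Neutrophil markers were higher with a median of 1.20 (adjusted p = 0.0081, and adjusted p = 0.91 with an estimated correlation). So were NRF2 targets (median 0.45), chemokines and cytokines (0.67) and stellate and matrix genes (0.41), with adjusted p = 0.021 to 0.036 (adjusted p = 0.58 to 0.91 with an estimated correlation), and without wild-type 552 these 3 calls ended (adjusted p = 0.34, 0.20 and 0.67).

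In all, 10 genes passed with age in wild-type mice, 7 higher and 3 lower. Tubb2a, Eif4ebp3 and Gpcpd1 were also among the 6 genes of knockout against wild-type liver at 2 months, in the same direction. These comparisons share the wild-type arrays. Simulations without any effect gave 0 shared genes, but the adjustment lets few genes pass where nothing changes. That 0 therefore does not measure what the shared arrays add. Across genes the 2 sets of changes had r = 0.62, against 0.60 in those simulations, so the shared arrays alone gave nearly as high an r. Knockout against hemizygous liver shares no array with the comparison by age, and 4 genes passed in both (Tubb2a, Lrfn3, Eif4ebp3 and Gpcpd1) where 0.0029 would be shared by chance. The count by age was 1655 without wild-type 641 (1554 lower), 16 without wild-type 552, 2 without wild-type 31, 0 without wild-type 34, 6 without knockout 64, and 17, 32 and 27 without non-tumor 1347, 934 and 638. With the slide as a block, joined through other groups, 108 passed, 0 of them among the 10, and with the scan day 81. Over the alternatives, these included, Gpcpd1 differed by -3.49 to -2.90, Eif4ebp3 by -3.73 to -2.58, Lrfn3 by 2.17 to 3.08 and Tubb2a by 2.52 to 4.05.

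The effect of the deletion was then compared between ages. Mcl1 differed by 0.77 between the effects at 12 and at 2 months (SE 0.48, adjusted p = 0.61; second probe 1.501), Gdf15 by -2.76 (SE 1.05, adjusted p = 0.49) and Afp by 2.34 (SE 0.997, adjusted p = 0.50). No list passed, with interferon response genes (median 0.61) and neutrophil markers (-1.69) nearest at adjusted p = 0.056. No gene passed limma's test, and 2523 of 26447 had an unadjusted p under 0.05, while without non-tumor animal 638 the count was 275. Across genes, which are not independent replicates, the changes of knockout liver at 2 and at 12 months had r = 0.13. At an unadjusted p under 0.05, 350 genes were higher at both ages, where independent tests would give 91.4. Lower at both ages were 109 genes, where independent tests would give 111. The tests at both ages use the same estimate of the spread, so they are not fully independent.

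Non-tumor knockout liver of 12 against 8 months was compared for progression with age. Interferon response genes were higher at 12 months in 17 of 19 (median 0.43, adjusted p = 1.3e-05) and T and NK cell markers had a median of 0.55 (adjusted p = 0.0014). Immediate early genes had a median of 0.61 (adjusted p = 0.0032) and S phase genes one of -0.37 (adjusted p = 0.012). These 4 calls were lost with an estimated correlation (adjusted p = 0.69 to 0.79). Without non-tumor animal 934 they ended (adjusted p = 0.14 for interferon response genes, 0.29 for T and NK cell markers, 0.61 for immediate early genes and 0.82 for S phase genes). Also higher were chemokines and cytokines (median 0.49), the BCL-2 family (0.30), unfolded protein and amino acid stress (0.30) and lipogenesis (0.28). So were endothelial (0.25) and macrophage markers (0.22), cholesterol synthesis (0.22) and death receptor and NF-kB genes (0.17). Fatty acid oxidation (-0.36) and DNA damage response genes (-0.28) were lower. These further lists had adjusted p = 0.0050 to 0.031 in camera (0.69 to 0.81 with an estimated correlation). Mcl1 differed by 0.08 (SE 0.31, and -0.16 in the second probe) and Afp by 1.496 (SE 0.64, adjusted p = 0.90). No gene passed limma's test, and 1408 of 26455 had an unadjusted p under 0.05. No slide held both ages.

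Tumor against non-tumor tissue of the same 7 animals asks what marks the tumors. Periportal genes, which serve urea and amino acid metabolism, were lower in tumors in 13 of 14 (median -0.45, adjusted p = 2.8e-06, and adjusted p = 0.34 with an estimated correlation), and their mean was lower in 7 of 7 animals by -0.36 (SD 0.28, n = 7). The histidine-degrading enzyme Hal differed by -0.62 (SE 0.16) and the urea cycle enzyme Ass1 by -0.60 (SE 0.18), each lower in 7 of 7 animals. Fetal and HCC-associated genes were higher in 14 of 16 (median 0.56, adjusted p = 2.8e-06, and adjusted p = 0.34 with an estimated correlation), with a mean of 0.87 (SD 0.74, n = 7) and 6 of 7 animals above 0. Among them Scd2 differed by 0.58 (SE 0.15, higher in 7 of 7). Afp differed by 1.90 (SE 0.87, adjusted p = 1.0), higher in the tumor of 6 of 7 animals.

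Cholesterol synthesis genes were higher in tumors in 18 of 19 (median 0.34, adjusted p = 2.0e-07, and adjusted p = 0.34 with an estimated correlation), with Sqle at 0.45 (SE 0.18) and Dhcr7 at 0.41 (SE 0.19), each higher in 6 of 7 animals. Mitosis genes had a median of 0.30 with 26 of 27 above 0 (adjusted p = 6.3e-08, and adjusted p = 0.50 with an estimated correlation), and their mean was higher in 4 of 7 animals. Beta-catenin and pericentral genes were below 0 in 18 of 18 (median -0.56, adjusted p = 5.0e-08, and adjusted p = 0.48 with an estimated correlation), with the mean lower in 4 of 7 animals. The ammonium channel gene Rhbg differed by -0.93 (SE 0.32) and Gulo, of vitamin C synthesis, by -0.62 (SE 0.23), both lower in 7 of 7. Hpd, of tyrosine breakdown, differed by -0.94 (SE 0.20) and the iron hormone Hamp by -0.95 (SE 0.25), lower in 7 of 7, and Cd9 by 0.68 (SE 0.15) and Gpam by 0.70 (SE 0.20), higher in 7 of 7. List members named for tumors were chosen by a small p in this same test, so their agreement over animals is partly a result of that choice. The macrophage list of Cd9 and the acute phase list of Hamp did not pass camera's test (adjusted p = 0.79 and 0.16). From the panel, Cdkn1a differed by 0.78 (SE 0.31, higher in 5 of 7), Bax by 0.45 (SE 0.20, higher in 6 of 7) and Mcl1 by -0.22 (SE 0.17, higher in 2 of 7; second probe -0.01).

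No gene passed limma's test in tumors, and 998 of 24010 had an unadjusted p under 0.05. Adjusted over the list alone 5 periportal genes were lower and 2 fetal and HCC-associated genes higher. In exact permutation within pairs, the means of periportal genes, of hepatocyte identity genes and of erythroid markers (too few in this model for camera), each lower in 7 of 7, reached the smallest possible p of 0.0156 (adjusted p = 0.16), and fetal genes and cholesterol synthesis p = 0.031 (adjusted p = 0.19). Animal 1347 alone had its tumor and non-tumor samples on different slides and scan days. In the 6 animals with both samples on the same slide the mean change was -0.35 for periportal genes and 0.77 for fetal genes. It was smaller there than in all 7 for beta-catenin and pericentral genes (-0.33 against -0.56) and for bile acid genes (-0.14 against -0.27). Smaller calls were lipogenesis (median 0.22), p53 targets (0.18), S phase (0.20), DNA damage response (0.08) and interferon response genes (0.10), and, lower, hepatocyte identity (-0.14) and bile acid genes (-0.34), with adjusted p = 0.0016 to 0.047 (adjusted p = 0.48 to 0.69 with an estimated correlation). Without animal 1347 the calls of S phase, DNA damage and interferon genes ended (adjusted p = 0.22, 0.41 and 0.53).

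**Figure D3:**
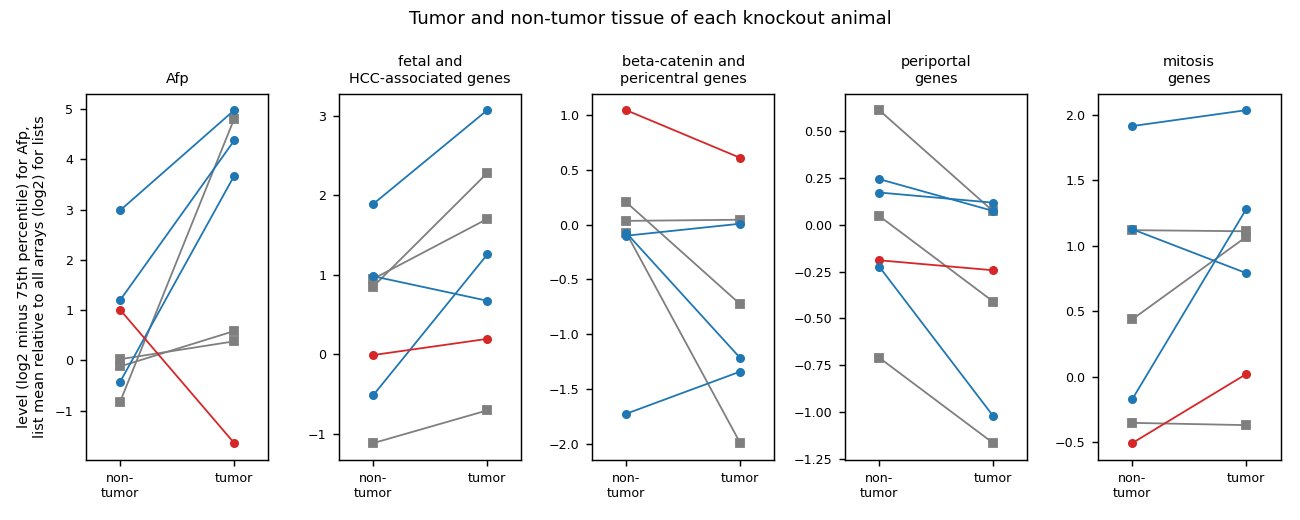
Tumor against non-tumor values of each of the 7 animals (log2, vertical axes) for Afp and for the means of fetal and HCC-associated, beta-catenin and pericentral, periportal and mitosis genes, with lines joining the samples of an animal, blue circles for 12 months, grey squares for 8 months and red for animal 638. Afp was higher in the tumor in 6 of 7 animals and the periportal mean lower in 7 of 7.

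Whether tumors at 12 months differ from non-tumor tissue otherwise than at 8 months was tested as an interaction. Interferon response genes had a mean change in tumors of 0.42 at 8 months (higher in 3 of 3 animals) and -0.08 at 12 months (higher in 1 of 4), and the interaction had a median of -0.49 (adjusted p = 1.5e-06, and adjusted p = 0.48 with an estimated correlation). T and NK cell markers had an interaction median of -0.83 (adjusted p = 5.0e-06, and adjusted p = 0.48 with an estimated correlation), and beta-catenin and pericentral genes one of 0.71 (adjusted p = 0.045, and adjusted p = 0.83 with an estimated correlation). Without animal 1347 these calls ended (adjusted p = 0.052, 0.058 and 0.76). The tumor and non-tumor samples of that animal alone lay on different slides and scan days, so those cannot be told apart from an effect of age here. No gene passed limma's test, and 1487 of 24010 had an unadjusted p under 0.05. Mcl1 had an interaction of -0.24 (SE 0.37), and the second probe one of 0.10.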

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

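The tests of 3 patterns described here were chosen only after the results were seen, except the test of an exchange in animal 638, which was fixed before its value was computed.

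Among 126 sets of 4 or 7 values examined, 9 held a value far apart from the rest, where chance gives about 1 in 20 sets, or 6.3. The sets were the 4 non-tumor arrays and the 4 tumor arrays at 12 months and the differences between tumor and non-tumor tissue in the 7 animals. Other groups were not examined. Gpc3, a fetal liver and cancer antigen, had a level of 1.20 in the non-tumor tissue of animal 702 (the other 3 lay between -4.38 and -3.60) and 0.78 in its tumor (others -4.64 to -3.96). The mean of cholangiocyte and progenitor markers was 1.08 in the tumor of animal 702 (others 0.08 to 0.24). The mean of NRF2 targets differed between tumor and non-tumor tissue by 0.995 in animal 702 (the other 6 lay between -0.30 and 0.26). In animal 1347 tumor and non-tumor tissue differed by 4.33 in Gpc3 (others -1.22 to 0.33), by 1.05 in the mean of interferon response genes (others -0.31 to 0.27) and by -1.32 in that of fatty acid oxidation genes (others -0.10 to 0.75). This animal alone had its tumor and non-tumor samples on different slides and scan days, which cannot be told apart from a difference between its tissues. In the non-tumor tissue of animal 638 Gdf15 had a level of 5.07 (others 1.97 to 2.25) and Cdkn1a 0.39 (others -0.56 to -0.41). Its tumor also had the highest Gdf15 level of the tumors at 12 months, 4.74, while Cdkn1a in its tumor, at 0.16, lay within the range of the others.

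The change in tumors differed by age in 11 lists by camera's interaction test, all lost with an estimated correlation (adjusted p = 0.46 to 0.83). At 12 months against 8 months the median was lower for T and NK cell markers (-0.83), interferon response (-0.49), cholangiocyte markers (-0.41), chemokines and cytokines (-0.24), death receptor and NF-kB genes (-0.22), the BCL-2 family (-0.19), cholesterol synthesis (-0.19) and endothelial markers (-0.19), and higher for beta-catenin and pericentral genes (0.71), fatty acid oxidation (0.48) and female-biased genes (0.31). When the age labels of the animals were permuted exactly, no list passed (p = 0.17 for interferon response and 0.31 for T and NK cell markers, where 0.0286 is the smallest possible).

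Mitosis genes and macrophage markers were higher in knockout than in hemizygous and wild-type liver at 2 months. The slide as the whole cause is argued against, since each knockout array lay above every array of another genotype on its slide, by at least 0.53 in the mean of either list, but only knockout 137 had arrays of its own age beside it (1.45 above in mitosis genes, 1.24 in macrophage markers), and knockout 64 and 69 lay beside wild-type 641 of 12 months, the array with the most probes above background. A lower share of hepatocytes stays open. In every knockout array the macrophage mean minus the endothelial mean lay at least 0.97 above every hemizygous and wild-type array of 2 months. These 2 marker lists thus did not rise alike, but the endothelial list had already been seen not to pass against wild-type liver. Stellate (median 1.23) and neutrophil lists (2.15) rose against wild-type liver and hepatocyte identity genes fell (-0.30), which goes with a lower share. The difference does not bear on mitosis genes, and more macrophages as such stay open too. Sex is argued against, since with the Xist level as a covariate both medians kept at least 88.5% of their values against wild-type and against hemizygous liver (mitosis genes 2.30 and 2.09, macrophage markers 1.43 and 1.08), although on the slide of knockout 137 sex differed with genotype. Division and macrophage gain after loss of Mcl-1 in hepatocytes is a candidate explanation, as a hypothesis, and which cells divide was not tested.

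Eif4ebp3, Gpcpd1, Bnip3 and Tubb2a changed in knockout liver at 2 months, and 3 of them also passed with age in wild-type mice, while Bnip3 differed by -1.05 with age and did not pass. The slide is argued against for knockout against hemizygous liver only. On one slide 4 of the 4 genes differed between knockout 137 and the hemizygous arrays by at least 50% of the change. Between slides they differed by less than that within knockout and within hemizygous mice of 2 months. Beside wild-type 641 of 12 months, knockout 64 and 69 differed by 0.22 in Eif4ebp3, 0.50 in Gpcpd1, -0.81 in Bnip3 and 0.76 in Tubb2a. Age differs there too, so those values decide nothing about the slide. Another phase of the daily cycle at collection may account for the 4 genes. In knockout against hemizygous liver 14 of 16 clock genes split between the 2 arms of the clock, with Arntl at 3.77 and Dbp at -3.90. Nr1d1 (0.84) and Cry1 (-0.71) went against their arm. In wild-type mice with age 13 of 16 split in this way, and Nr1d1 (1.32), Nfil3 (-0.28) and Cry1 (-0.18) went against their arm. Loss of Mcl-1 and such a phase cannot be told apart for these 4 genes, because no collection time is given in the labels; that 4 of the 4 also differed between wild-type mice of 12 and 2 months by at least 50% of their change in knockout against hemizygous liver decides nothing, since 3 were known to pass with age when this was tested. At 12 months the 4 genes differed by only -0.37 to 0.64 between non-tumor knockout and wild-type liver, with Mcl1 at -1.69 and 16 of 16 clock genes split by arm, which goes against both explanations without excluding either, since 3 of the genes had already changed with age in wild-type mice.

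Animal 638 lay apart from the other non-tumor arrays at 12 months, with a mean correlation across genes of -0.06 with the other 3 against 0.21 with the wild-type arrays. It was not alone in this: wild-type 552 correlated more with the knockout arrays (0.18) than with the other wild-type arrays (0.05), and wild-type 641 with neither (-0.24 and -0.32). A wild-type liver in its place is argued against, since its Mcl1 level was 1.51 below the lowest wild-type array, and a dim array is argued against, since 64.1% of its probes were well above background (others 61.1% to 70.5%). An exchange of its tumor and non-tumor samples may be the cause: its tumor minus non-tumor differences ran against the mean of the other animals (r = -0.21 across genes, which are not independent replicates; others -0.12 to 0.13), and Afp was lower in its tumor (-1.64 against 1.01). That evidence is weak, since its periportal genes were lower in the tumor, like those of the other 6 animals, and biological variation between animals was not tested. Its Gdf15 level was high in both tissues (5.07 in non-tumor tissue, 4.74 in the tumor), which an exchange would not produce.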

How the results depend on the processing

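Chosen only after the data were seen were the model without the second scan day and, in list tests, the slide block and the Xist covariate. Of 255 counts under alternatives 158 stayed within 1.5 times the reported one and 97 did not. Direction was compared only for results that had passed as reported, and the others were judged by their side of the threshold alone. Of 3326 list results 2816 stayed the same in this sense, 348 were weaker, 150 stronger and 12 reversed. Of 22319 results for named genes 21968 stayed the same, 147 were weaker, 204 stronger and 0 reversed. Most of them passed neither as reported nor under the alternative, so their direction was not compared. Of the genes that had passed, Mcl1, Tubb2a, Eif4ebp3 and Gpcpd1 in knockout against wild-type liver passed in 10 of 17 alternatives and Bnip3 in 9 of 17. In knockout against hemizygous liver S100a9 passed in 11 of 18, Tubb2a, Map2k6, Gpcpd1 and Eif4ebp3 in 10 of 18, Fkbp5 in 9 of 18, S100a8 in 9 of 17 and Phlda2 in 8 of 18 (log2 1.53 with normexp). At 12 months Dmrta1 passed in 17 of 18 and B3galnt1 and Lpin2 in 14 of 19, and with age Raet1e, Gpcpd1 and Eif4ebp3 in 13 of 17, Tubb2a and Lrfn3 in 11 of 17 and Dmrta1 in 12 of 16. With no animal block 0 genes passed for tumor against non-tumor tissue (limma, 238 at an unadjusted p under 0.05).

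The counts below are of genes past the threshold, named as knockout against wild-type at 2 months, knockout against hemizygous, hemizygous against wild-type, 12 months (non-tumor knockout against wild-type), age (wild-type 12 against 2 months) and interaction (effect of the deletion at 12 against 2 months). Unless stated otherwise the cause was not tested. With normexp and quantile normalisation they were 14 for knockout against wild-type, 73 for knockout against hemizygous, 454 at 12 months, 29 with age and 7 for the interaction. With quantile normalisation of the processed signal they were 23 for knockout against wild-type, 2 for hemizygous against wild-type, 61 with age and 1 for the interaction. The authors' series matrix gave 17, 52, 211, 24 and 2 for knockout against wild-type, knockout against hemizygous, 12 months, age and interaction. The filter on every array gave 17, 30, 413, 33 and 1 for the same 5, and no filter gave 1 for hemizygous against wild-type. Trend and robust options gave 32, 64, 313, 48 and 1 for the same 5. The slide as a block gave 40 for knockout against wild-type, 18 for hemizygous against wild-type, 41 for knockout against hemizygous, 2 at 12 months (random block) and 108 with age. The scan day gave 3431 at 12 months, 81 with age and 191 for the interaction. All 25 arrays in one model gave 21 for knockout against wild-type and 28 for knockout against hemizygous. With only the groups compared, which leaves fewer arrays to estimate the spread, limma called 0 genes for knockout against wild-type, knockout against hemizygous, 12 months and age (4016, 4442, 2379 and 2024 at an unadjusted p under 0.05). The Xist covariate gave 27 for knockout against wild-type, 8 at 12 months and 18 with age. Without the second scan day the counts were 12 for knockout against wild-type, 3010 at 12 months, 44 with age and 9 for the interaction.

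Leaving out 1 animal gave 0 to 24 genes for knockout against wild-type, 0 to 2 for hemizygous against wild-type, 0 to 28 for knockout against hemizygous, 1 to 2729 at 12 months, 0 to 1655 with age, 0 to 275 for the interaction and 0 to 1 for non-tumor liver of 12 against 8 months. Where a group kept 1 array, that array is assumed to vary like the other groups.

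Reversal here is of the direction in camera's test, and the values are medians. Lists that reversed with the slide as a block were, for knockout against wild-type, DNA damage response -0.0034, S phase -0.26 and acute phase -0.12, for knockout against hemizygous S phase -0.14, for hemizygous against wild-type lipogenesis 0.0047 and macrophage markers 0.0065 (both medians shrank and stayed positive), and with age NRF2 targets -0.21 and stellate cell genes -0.23. Reversed without 1 animal were endothelial markers in knockout against hemizygous liver (-0.50 to 0.024, the highest without knockout 64), cholesterol synthesis (-0.067 to 0.37, the lowest without 1347) and macrophage markers (-0.32 to 0.61, the lowest without 934) in non-tumor liver of 12 against 8 months, and interferon response in tumors (-0.023 to 0.14, the lowest without 1347).

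Signal was 2.65 to 5.55 times the local background, and where no array of a group was well above background only a bound on the change is given.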

Other observations

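The counts of clock genes by arm were chosen only after the result was seen, and the counts under other splits of the samples were fixed beforehand.

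The clock list as a whole did not pass camera's test in older knockout liver, yet its genes split by arm. In non-tumor knockout against wild-type liver at 12 months 16 of 16 clock genes took the sign of their arm, with Dbp at -2.04, Nr1d1 at -2.23 and Arntl at 1.02. In wild-type mice of 12 against 2 months Ciart differed by -6.25, Arntl by 3.51 and Dbp by -2.91. Nr1d1 went against its arm there (1.32), as it did in knockout against hemizygous (0.84) and against wild-type liver (1.27) at 2 months.

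Samples were also split in other ways into groups of the same sizes. For knockout against hemizygous liver the real split gave 14 genes and the highest other gave 2, and 10 splits are too few for a share under 0.05 (the real one alone, 1 of 10, is as large). For non-tumor knockout against wild-type liver at 12 months chance cannot be excluded: 4 of 35 splits gave at least the real 5 genes. The highest other split, which puts animal 638 with the 3 wild-type mice, gave 3610, and one with wild-type 552 beside non-tumor 1109, 702 and 793 gave 2114, so these arrays have a structure other than genotype. At an unadjusted p under 0.05, chance cannot be excluded for non-tumor liver of 12 against 8 months (19 of 35 splits as large, real 1408, highest other 2908), for tumor against non-tumor tissue (33 of 64 exchanges within animals, real 998, highest other 2528) or for the tumor change by age (9 of 35, real 1487, highest other 2748). Exchanging animal 638 alone gave 1659, animal 793 alone 1714 and animal 934 alone 1074, while animals 1287, 1109 and 702 alone gave 585, 550 and 558. A rise over the real count is thus not particular to animal 638.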
